A study of Arabidopsis thaliana with 24 samples.

How the data were processed

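Biotin-labelled total RNA of 24 Arabidopsis samples had been hybridised to one-colour arrays. The deposited values are intensity on a linear scale, with a single value per probe set and array, and the submitters' processing notes name MAS5, whose version is not given in the sources used here. Checked on the values, the 2% trimmed mean of every array equalled 100, so the authors had scaled the arrays to a common target. Samples were grouped by the set number in the labels, 8 sets of 3. Of 22810 probe sets 64 controls were left out, except for the RNA quality ratios and spike-in levels. A probe set was tested if at least 3 arrays exceeded an intensity of 22.9, the 40th percentile of all values, which left 15471 of 22746.

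Intensities were turned into log2 values after adding a pseudocount of 6.75, the 20th percentile of the table, with no further normalization. Folds and differences of genes near that level are therefore understated. limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8, fitted the 8 set means to all 24 arrays (lmFit and eBayes, two-sided, 16 residual and 4.77 prior degrees of freedom). P-values were adjusted by the method of Benjamini and Hochberg over all probe sets tested, and a call means an adjusted p under 0.05. Differences are first set minus second set, higher and lower refer to the first set, and the difference of the sucrose effects is set ATGE_101 minus 100 less set 97 minus 96. A moderated F test covered any difference among sets 22, 23 and 24. A rank test of 3 against 3 arrays cannot go below a two-sided p of 0.1, which is why the pooled model was used.

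Probe sets were named from the annotation provided: 13513 named 1 gene, 503 several and 8730 none, and 1586 carried a symbol, 1218 of them among those tested. Most genes have no symbol there, so genes named by size come from that part. No genome build is used here and no coordinates are given. The comparisons, tests, alternatives, 24 gene lists and the rule for named genes were chosen before the data were examined. By that rule the 6 highest and 6 lowest differences were named in each of 6 main comparisons, and the 4 highest and 4 lowest in the others, among called probe sets with 1 symbol whose arrays did not overlap. Up to 4 members of fixed lists, and 2 that went against them, were added. The requirement on overlap was not applied to the difference of the sucrose effects. Of 433 loci in the fixed lists 51 had a probe set that names that gene alone and 46 were tested, and 9 of the 24 lists had the 3 genes needed. A list member is called measured here if such a probe set was tested. The other members may lie among the probe sets without a gene name, so nothing is known here of their levels. Further lists, by gene family or organelle genome, were drawn up after the annotation was read and before any list test; after the first tests 1 was removed and another renamed, which left 24. The Aux/IAA list had 2 genes tested, under the 3 needed, so 23 were tested. Members of these are named by the same ordering, chosen after values were seen.

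Lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (the highest mean) and 8292 genes as background, adjusted over 32 lists in each comparison. Of 53 called lists 3 held with an estimated correlation. Alternatives were the pseudocount divided by 4 (1.69) and 4 times it (27), no filter, a stricter filter (61.6), quantile normalization, a common 75th percentile, only the groups compared in the fit, a trend with robust fitting, the replicate letter as a block and leaving out each replicate. Leaving out arrays 24 A, 100 A and ATGE_101_A together was chosen after seeing the data. Where an array was left out, the remaining pair shares the spread of all sets. The procedure was tested on simulated data, with 50 probe sets changed at each size. It recovered 62%, 92%, 98% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 10 false calls (5.38% of calls) and 0 in an unchanged comparison. A list shifted by 0.5 was called, as was 1 of 31 other lists. Each simulated probe set had the same spread in all sets and was drawn independently of the others. These simulations therefore cannot show errors that come from unequal spread between sets or from correlated genes. The number of arrays limits the precision.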

Results

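Transcript levels were measured in green tissue of Arabidopsis thaliana, accession Col-0, with biotin-labelled total RNA on 24 one-colour oligonucleotide arrays. The arrays form 8 sets of 3, called here by the numbers in their labels, except that 1 of them keeps its full label, ATGE_101, with replicates A, B and C. All plants grew in continuous light. The labels do not say whether the arrays of a set come from separate cultures, so every p-value here measures only the spread between these samples. Set 7 is the green part of seedlings on soil at 23 °C and 65% relative humidity. Sets 22, 23 and 24 are whole plants on the same soil regime, harvested past the transition and not yet bolting. Their labels are identical and speak of developmental drift, so nothing but the set number separates them here. Sets 96, 97, 100 and ATGE_101 are the green parts of seedlings grown at 20 °C on 0.5x GM, as the labels call the medium, and sets 97 and ATGE_101 had 5% sucrose added. A note on sets 96 and 97 says that most of their plants looked like the 7-day-old plants of set 7. The number of arrays limits the precision. Each array had a trimmed mean intensity of 100, a median between 35.4 and 43.1 and a highest value between 3240 and 7373, and the median intensity by set lay between 36.1 in set 96 and 42.7 in set ATGE_101. Arrays of the same set correlated at a mean r of 0.975 (set 22) to 0.99 (set 97) across probe sets.

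Intensities are given as mean ± SD over the 3 arrays of a set (n = 3), and differences as log2 values with limma's adjusted p. For every gene named by the size of its change outside the difference of the sucrose effects, all arrays of either side lay above all arrays of the other, which chance gives in 10% of splits of 3 against 3.

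The first question is what 5% sucrose does to seedlings on the same medium. With sucrose, set 97 had less transcript of the enzymes that break down leucine. MCCA (AT1G03090) and MCCB (AT4G34030), the subunits of methylcrotonyl-CoA carboxylase, changed by -2.01 and -0.94 on the log2 scale (adjusted p = 6.4e-12 and 1.4e-05), and IVD (AT3G45300), isovaleryl-CoA dehydrogenase, fell by 1.4 (adjusted p = 4.8e-09). MCCA stood at 787 ± 26.2 without and 190 ± 8.17 with sucrose. These 3 genes are the measured members, out of 26, of the list of genes induced by sugar starvation and darkness. Measured means tied to a tested probe set by the annotation, so other members may still be on the arrays. All 3 were lower, over all genes and adjusted over the list alone (camera adjusted p = 6.9e-06), and the list kept its call with an estimated correlation (adjusted p = 0.027). ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle and the single measured member of the seed and late embryo marker list, stood at 131 ± 18 in set 96 and 29.2 ± 8.15 in set 97, a log2 difference of -1.95 (adjusted p = 1.2e-10).

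The largest rise of a named gene in set 97 was in BGLU28 (AT2G44460), a beta-glucosidase, from 22.9 ± 1.35 to 204 ± 9.43 (log2 difference 2.83, adjusted p = 4e-12). The chitinases CHI (AT2G43570) and ChiC (AT4G19810) rose by 2.21 and 1.56 (adjusted p = 2e-04 and 5.2e-08). EXPA8 (AT2G40610), an expansin, rose from 61.9 ± 4.8 to 302 ± 25.6, and GH9B8 (AT2G32990), a glycosyl hydrolase of family GH9, from 11 ± 3.58 to 48.5 ± 2.52. SAL2 (AT5G64000) rose from 7.01 ± 2.12 to 47.4 ± 4.51. Other genes of the cell wall moved the other way: XTH18 (AT4G30280), a xyloglucan endotransglucosylase/hydrolase, had the largest fall of a named gene, from 871 ± 39.4 to 98.8 ± 15.2 (log2 difference -3.07, adjusted p = 3.1e-06), and the expansin-like gene EXLA1 (AT3G45970) fell by 1.95 (adjusted p = 5.5e-07). B120 (AT4G21390), a receptor-like kinase, and CCR2 (AT1G80820), cinnamoyl-CoA reductase, both fell by 1.9 on that scale, CCR2 to 5.06 ± 3.13, near the floor of the arrays.

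Some lists of gene families and of plastid-encoded genes were called in set 97. Of 11 beta-glucosidases 5 were higher and 1 was lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.022; adjusted p = 0.16 with an estimated correlation), with BGLU44 (AT3G18080) at 329 ± 42.8 without and 738 ± 43.2 with sucrose. Of 6 glutathione S-transferases of the tau class 4 were higher (4 over the list alone, camera adjusted p = 0.038; adjusted p = 0.16 with an estimated correlation), with GSTU27 (AT3G43800) up by 1.07. Of 15 serine carboxypeptidase-like genes 6 were higher and 1 was lower (8 and 1 over the list alone, camera adjusted p = 0.023; adjusted p = 0.34 with an estimated correlation), led by scpl35 (AT5G08260) at +1.34. Of 9 genes numbered GH, 4 were higher (6 over the list alone, camera adjusted p = 0.017; adjusted p = 0.16 with an estimated correlation). This list was drawn up by symbol and joins GH3 genes with glycosyl hydrolases of family GH9, so it is not a single family. Some members of these lists lost their calls (adjusted p, then the range over alternatives): BGLU46 (AT1G61820) without array 96 B, 96 C, 97 B or 97 C (0.052, 0.095, 0.068 and 0.071; range 0.0021 to 0.18), the lower beta-glucosidase, and GSTU16 (AT1G59700) without array 96 A, 96 B, 97 A or 97 C (0.072, 0.11, 0.078 and 0.11; range 0.024 to 0.11). The same held for SCPL34 (AT5G23210) without array 96 B, 97 A or 97 C (0.065, 0.052 and 0.054; range 0.0045 to 0.065), the lower carboxypeptidase-like gene, and GH9B7 (AT1G75680) without array 96 A, 96 B, 96 C, 97 A, 97 B or 97 C (0.055, 0.086, 0.15, 0.11, 0.099 and 0.074; range 0.013 to 0.15). Of 33 plastid-encoded photosynthesis genes 4 were lower and none higher, with 29 not called (1 over the list alone, camera adjusted p = 0.0041; adjusted p = 0.73 with an estimated correlation), among them psbD (ArthCp017) at -0.52 and petD (ArthCp054) at -0.52. Plastid-encoded genes of the NADH dehydrogenase-like complex were lower in 2 of 10 (1 over the list alone, camera adjusted p = 0.024; adjusted p = 0.51 with an estimated correlation). Those of gene expression were lower in 2 of 19 (2 over the list alone, camera adjusted p = 0.017; adjusted p = 0.73 with an estimated correlation). The psbD and petD calls were lost without array 96 B (adjusted p = 0.067 and 0.07; range over alternatives 0.0037 to 0.067 and, for petD, range over alternatives 0.0021 to 0.07). The other 2 called photosynthesis genes, psaA (ArthCp022) and psbE (ArthCp039), lost their calls without any single array of either set (adjusted p = 0.06 to 0.16 and 0.05 to 0.14; range over alternatives 0.0039 to 0.16 and, for psbE, range over alternatives 0.015 to 0.14), so that without array 96 B none of the 4 was called. Of the other plastid-encoded genes called, calls were lost for ndhA (ArthCp079) without array 96 A, 96 B, 96 C, 97 A or 97 B (0.072, 0.13, 0.062, 0.097 and 0.19; range 0.016 to 0.19), ndhH (ArthCp080) without array 97 B (0.054; range 0.0038 to 0.054) and rpl14 (ArthCp059) without array 96 C or 97 B (0.071 and 0.074; range 0.00099 to 0.074), where values are adjusted p and ranges run over alternatives. All 3 lists of plastid-encoded genes lost their call after quantile normalization, where each had a camera adjusted p of 0.24.

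Members of the cold, drought and abscisic acid list parted in set 97. COR47 (AT1G20440) fell by 0.75 (adjusted p = 2.1e-05), while COR15A (AT2G42540) and COR15B (AT2G42530) had log2 differences of 0.44 and 0.6 (adjusted p = 0.05 and 0.04, the first just under the threshold). The list's median was 0.44 and its mean 0.10, while the test pointed down with a camera adjusted p of 0.81; adjusted over the list alone 2 were higher and 1 lower. The COR15B call was lost without any single array of either set (adjusted p = 0.056 to 0.1). The COR15A call was lost without array 96 A, 96 C, 97 A or 97 B (0.12, 0.17, 0.093 and 0.21). Over all alternatives adjusted p ranged from 0.0008 to 0.1 and from 0.023 to 0.21. APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, rose from 13.8 ± 3.57 to 35.9 ± 3.74 (adjusted p = 2.2e-05), the only called member of 3 in its list (2 over the list alone, camera adjusted p = 0.51). The ribosomal protein gene RPL4D (AT5G02870) rose by 0.29, the only called member of 3 (1 over the list alone, camera adjusted p = 0.51), and its call was lost without array 96 B (adjusted p = 0.057, range over alternatives 0.00081 to 0.057). None of 3 light-harvesting and photosynthesis genes was called (0 over the list alone, camera adjusted p = 0.58). In all, 5118 of 15471 probe sets were called between sets 97 and 96, 3239 higher and 1879 lower with sucrose, of which 336 and 309 changed at least 2-fold. The share of higher calls was 63.3% as deposited, 56% with a common 75th percentile and 54.5% after quantile normalization.

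The second pair of medium sets puts the same question to seedlings without the note on resemblance. In set ATGE_101 the leucine breakdown genes were again lower than in its control, set 100: MCCA changed by -0.79, IVD by -0.59 and MCCB by -0.52 (adjusted p = 1.1e-05, 0.00061 and 0.0082). That is 3 of 3 list members, also adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.088 with an estimated correlation). The MCCB call was lost without array ATGE_101_C (adjusted p = 0.053, range over alternatives 0.0027 to 0.053). BGLU28 rose from 63.3 ± 4.85 to 361 ± 20.2 and ChiC from 23.8 ± 4.17 to 90.7 ± 5.1 (adjusted p = 1.7e-10 and 6.3e-08). OCT1 (AT1G73220), an organic cation and carnitine transporter, had the largest rise of a named gene, from 0.902 ± 0.115, at the floor, to 38.5 ± 2.53 (log2 difference 2.56, adjusted p = 3.6e-13). That rank depends on the pseudocount: with 4 times it OCT1 rose by 1.23 and BGLU28 by 2.1. GILT (AT4G12960), a thiol reductase, rose by 1.91 (adjusted p = 9.2e-06), and THI2.1 (AT1G72260), a thionin of the jasmonate list, from 83.9 ± 2.98 to 213 ± 42.5.

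Falls in set ATGE_101 were in PDF1.4 (AT1G19610), a defensin-like gene (-1.65, adjusted p = 9.8e-07) and in CSLA03 (AT1G23480), of the cellulose synthase-like family (-1.53, adjusted p = 3.8e-08). Other falls were in XTH16 (AT3G23730) (-1.33, adjusted p = 8.7e-05), in the calmodulin-like gene CML42 (AT4G20780) (-1.3, adjusted p = 6.6e-08) and in MSRB9 (AT4G21850), a methionine sulfoxide reductase (-1.24, adjusted p = 5e-04). XTH18 stood at 801 ± 58.5 without and 302 ± 39.6 with sucrose (adjusted p = 0.014), a call lost without array 100 C (0.05, just over the threshold) or ATGE_101_B (0.056). The arrays of these sets lay well apart for XTH18, at 755 to 867 without and 264 to 343 with sucrose. Its adjusted p uses the spread pooled over all sets, including those on soil, where XTH18 ran from 0.487 to 80.5. SAG29 (AT5G13170), of the senescence list, had a log2 difference of 1.3 (adjusted p = 0.04), lost without array 100 B, 100 C, ATGE_101_A, ATGE_101_B or ATGE_101_C (0.21, 0.074, 0.077, 0.1 and 0.091). Over all alternatives adjusted p ranged from 5.8e-05 to 0.099 for XTH18 and from 0.014 to 0.21 for SAG29. COR15A rose by 1.08 (adjusted p = 0.00011), 1 of 3 in its list (1 over the list alone, camera adjusted p = 0.068). APL3 rose by 0.86 (adjusted p = 0.00051), 1 of 3 in its list (1 over the list alone, camera adjusted p = 0.19). AGL24 (AT4G24540), a MADS-box promoter of flowering, had a log2 difference of 0.42 (adjusted p = 0.032), 1 of 3 floral promoters (1 over the list alone, camera adjusted p = 0.33). The AGL24 call was lost without array 100 A, 100 B, ATGE_101_A or ATGE_101_C (adjusted p = 0.14, 0.058, 0.078 and 0.11; range over alternatives 0.0059 to 0.22).

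Of 11 beta-glucosidases 3 were higher and 1 was lower in set ATGE_101 (5 and 1 over the list alone, camera adjusted p = 0.0068; adjusted p = 0.088 with an estimated correlation), with BGLU45 (AT1G61810) at +1.19 and BGLU44 at +0.69. Of 9 genes numbered GH, 3 were higher (3 over the list alone, camera adjusted p = 0.024; adjusted p = 0.15 with an estimated correlation). In that list a call was lost for GH9B5 (AT1G19940) without array 100 A, 100 B, ATGE_101_A, ATGE_101_B or ATGE_101_C (0.17, 0.1, 0.059, 0.2 and 0.071; range 0.027 to 0.2), with adjusted p and the range over alternatives. Of 12 mitochondrion-encoded genes 3 were lower and none higher (4 over the list alone, camera adjusted p = 0.014; adjusted p = 0.12 with an estimated correlation), nad6 by -0.65, nad4L by -0.42 and ccb452 by -0.32. The last was not called without array 100 A, 100 B, 100 C, ATGE_101_A, ATGE_101_B or ATGE_101_C (adjusted p = 0.15, 0.058, 0.075, 0.14, 0.062 and 0.083; range over alternatives 0.02 to 0.26). The ratio of the 3' to the 5' actin control probe sets was 8.62 ± 0.426 in set ATGE_101 and 3.6 ± 0.789 in set 100, while that of GAPDH was 1.33 ± 0.194 and 1.39 ± 0.179. That of ubiquitin was 2.31 ± 0.414 and 2.32 ± 0.49. In all 2578 probe sets were called, 1531 higher and 1047 lower with sucrose, of which 188 and 127 changed at least 2-fold. The excess of higher calls goes with the scaling: 59.4% were higher as deposited, 49.6% with a common 75th percentile (1270 higher and 1291 lower) and 50.8% after quantile normalization. Without arrays 100 A and ATGE_101_A, which had the lowest BioB spike-in intensities (22.6 and 38), and without array 24 A, 1800 were called, an alternative chosen after seeing the data.

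The sucrose effects of the pairs were compared with each other. They share no array, and across 15471 probe sets their log2 differences correlated at r = 0.502 (Spearman's rho 0.413); genes are not independent replicates. Of the probe sets called in both, 838 were higher in both (321 from independent lists), 532 lower in both (127) and 86 went opposite ways (405). The difference of the effects was called for 1855 probe sets, 831 higher and 1024 lower in the second pair, and for 1360 of them (73.3%) the effect was smaller in size in the second pair. For 1108 of the 1855 the estimated effects pointed in opposite directions, with both called for 86. MCCA and IVD were among those whose fall was smaller there, by 1.22 and 0.81 (adjusted p = 1.3e-05 and 0.0017). For the sugar starvation list 2 of 3 members differed (3 over the list alone, camera adjusted p = 0.00092; adjusted p = 0.14 with an estimated correlation). OCT1 and GILT rose in set ATGE_101 while in the first pair their log2 differences were 0.2 and 0.06, neither called. The differences of the effects were 2.37 and 1.86 (adjusted p = 1.5e-09 and 0.0013). UGT73B4 (AT2G15490), a glycosyltransferase, and ICL changed with sucrose in set 97 by -1.62 and -1.95 but had log2 differences of 0.34 and -0.08 in the second pair (adjusted p of the difference = 5.5e-05 and 3.2e-07), where ICL was already near the floor without sucrose (1.67 ± 0.459).

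NRT2.5 (AT1G12940), a nitrate transporter, rose by 1.22 in set 97 and had a log2 difference of -0.4 in set ATGE_101 (difference -1.62, adjusted p = 0.00065). EXPA8 rose in both, by 2.17 and 0.88 (difference -1.29, adjusted p = 0.0039), and CSLA03 went from -0.28, not called, to -1.53 (difference -1.25, adjusted p = 0.00011). SAL2 rose by 1.98 in set 97 against 0.64 in set ATGE_101 (difference -1.35, adjusted p = 0.032). That call was lost without array 96 A, 96 C, 97 A, 97 B, 97 C, 100 A, 100 C or ATGE_101_C, with adjusted p between 0.05, just over the threshold, and 0.083 (range over all alternatives 0.001 to 0.083). Of 33 plastid-encoded photosynthesis genes 2 had a higher difference (2 over the list alone, camera adjusted p = 0.04; adjusted p = 0.84 with an estimated correlation), psbB (ArthCp049) by 1.14 and psbD by 0.76. The psbD call was lost without array 96 B (adjusted p = 0.054) or 97 A (0.05, just over the threshold; range over alternatives 0.008 to 0.084). The 8 genes named here by size were taken without the requirement that arrays do not overlap. With the 12 arrays of these sets alone in the fit, 3076 probe sets were called. Of the 4 sets, ATGE_101 stood out by its actin 3' to 5' ratio, 8.62 ± 0.426 against 4.12 ± 1.92, 3.8 ± 0.374 and 3.6 ± 0.789 in sets 96, 97 and 100. Its GAPDH and ubiquitin ratios were not raised.

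**Figure D1:**
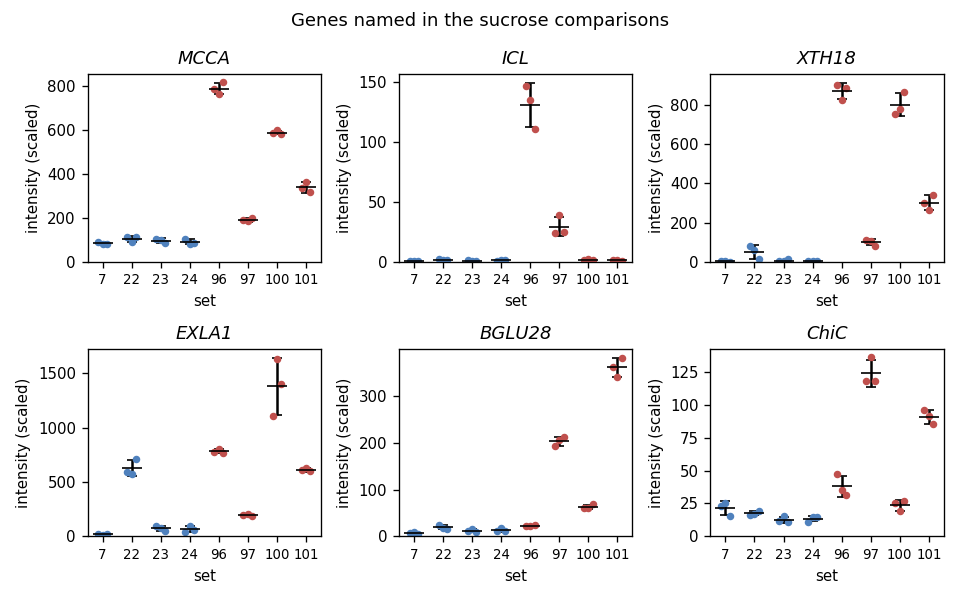
Intensity (scaled, linear axis) of 6 genes named in the sucrose comparisons in each set; blue points are arrays of plants on soil (sets 7, 22, 23 and 24), red points arrays of seedlings on medium, and the horizontal line and bars are mean ± SD of 3 arrays. MCCA, ICL, XTH18 and EXLA1 were lower in set 97 than in set 96, for XTH18 98.8 ± 15.2 against 871 ± 39.4, and BGLU28 and ChiC were higher in sets 97 and ATGE_101 than in sets 96 and 100.

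Sets 100 and 96 carry the same conditions in their labels and differ in the note of set 96 on resemblance to set 7. AGL24 stood at 68.7 ± 7.91 in set 100 and 4.78 ± 2.33 in set 96 (log2 difference 2.73, adjusted p = 3.2e-12). All 3 measured floral promoters were higher (3 over the list alone, camera adjusted p = 0.0064; adjusted p = 0.092 with an estimated correlation), AGL42 (AT5G62165) by 0.79 and FD (AT4G35900) by 0.8. The AGL42 call was lost without array 96 B (adjusted p = 0.064). The FD call was lost without array 96 A, 96 B, 100 A, 100 B or 100 C (0.16, 0.05, 0.064, 0.063 and 0.074). Over all alternatives adjusted p ranged from 0.0045 to 0.064 for AGL42 and from 0.007 to 0.16 for FD. The jasmonate and wound list rose in 3 of 3 members (3 over the list alone, camera adjusted p = 0.005; adjusted p = 0.19 with an estimated correlation): THI2.1 by 2.5 and the defensin genes PDF1.2 (AT5G44420) and PDF1.2b (AT2G26020) by 2.54 and 2.48 (adjusted p = 1.1e-06, 3.5e-05 and 0.00046). Probe sets of the PDF1.2 copies can share signal. The cold list rose in 3 of 3 as well (3 over the list alone, camera adjusted p = 0.005; adjusted p = 0.19 with an estimated correlation), with COR15A at 51.4 ± 8.68 against 11.7 ± 2.34, COR15B up by 1.81 and COR47 by 0.49.

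HIS1-3 (AT2G18050), a linker histone, rose from 29.2 ± 0.679 to 179 ± 17.5 and TBL38 (AT1G29050), of the trichome birefringence-like family, from 52.8 ± 0.376 to 301 ± 5.87 (adjusted p = 5.1e-09 and 1.2e-12). ICL had the largest fall of a named gene, -4.02, from 131 ± 18 to 1.67 ± 0.459 (adjusted p = 1e-15). WRKY6 (AT1G62300) changed by -1.86, HMT-1 (AT3G25900), a homocysteine methyltransferase, by -1.82, the thionin THI2.2 (AT5G36910) by -1.6, UGT73B4 by -1.57 and UGT76C2 (AT5G05860) by -1.48 (adjusted p = 3.2e-06, 1e-09, 0.0023, 1.1e-06 and 0.00017). Of 7 anthocyanin and flavonoid genes 2 were lower (2 over the list alone, camera adjusted p = 0.027; adjusted p = 0.26 with an estimated correlation), CHIL (AT5G05270) by -1.23 and UGT78D1 (AT1G30530) by -0.44. UGT78D1 lost its call without array 96 B (adjusted p = 0.05, just over the threshold; range over alternatives 0.0041 to 0.05). Of 31 glycosyltransferases of the UGT family 12 were lower and 3 higher (13 and 3 over the list alone, camera adjusted p = 0.0064; adjusted p = 0.19 with an estimated correlation). Of 15 serine carboxypeptidase-like genes 7 were higher (7 over the list alone, camera adjusted p = 0.018; adjusted p = 0.19 with an estimated correlation), scpl31 (AT1G11080) by 1.63. Among 9 genes numbered GH, 5 were higher (5 over the list alone, camera adjusted p = 0.035; adjusted p = 0.19 with an estimated correlation), GH9B13 (AT4G02290) by 1.78. Of 5 WRKY genes 3 were lower (3 over the list alone, camera adjusted p = 0.025; adjusted p = 0.26 with an estimated correlation), WRKY47 (AT4G01720) by -0.94.

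Transcripts of the organelle genomes moved apart in set 100. Of 12 mitochondrion-encoded respiration genes 9 were higher and 1 was lower (10 and 1 over the list alone, camera adjusted p = 1.8e-05). The list kept its call with an estimated correlation (adjusted p = 0.019). In this list, nad4L stood at 69.5 ± 4.14 against 29.2 ± 2.34, ccb452 at 275 ± 20.5 against 118 ± 13.4, and nad9 and nad1 were higher by 1.0 and 0.99. The lower member, ccb382, had a log2 difference of -0.44 (adjusted p = 0.044) and was not called without any single array of either set (0.068 to 0.13; range over alternatives 0.0041 to 0.13). Of 33 plastid-encoded photosynthesis genes 9 were lower and none higher (13 over the list alone, camera adjusted p = 1.4e-05; adjusted p = 0.26 with an estimated correlation), led by psbB at -0.81. Genes of the plastid-encoded NADH dehydrogenase-like complex were lower in 2 of 10 (2 over the list alone, camera adjusted p = 0.021; adjusted p = 0.26 with an estimated correlation). Plastid-encoded genes of gene expression were lower in 4 of 19 (0 over the list alone, camera adjusted p = 0.005; adjusted p = 0.37 with an estimated correlation). These 2 list calls were lost after quantile normalization (camera adjusted p = 0.14 and 0.1). Without array 100 A, which had the lowest BioB spike-in intensity of all arrays (22.6), all 4 called genes of gene expression lost their calls. There rps2 moved from -0.33 to -0.17, rpoC1 from -0.31 to -0.15 and rpl16 from -0.37 to -0.22. Of the photosynthesis genes, petL moved from -0.53 to -0.27 and atpH from -0.37 to -0.23. In full, with adjusted p and the range over alternatives, calls were lost for rpl14 without array 96 B, 96 C or 100 A (0.074, 0.13 and 0.076; range 0.0022 to 0.13), rpl16 (ArthCp060) without array 96 B, 96 C or 100 A (0.077, 0.12 and 0.22; range 0.02 to 0.22), rps2 (ArthCp011) without array 96 A, 96 B, 96 C or 100 A (0.11, 0.05, 0.12 and 0.3; range 0.02 to 0.3) and rpoC1 (ArthCp013) without array 96 A, 96 B, 96 C, 100 A or 100 C (0.061, 0.16, 0.073, 0.33 and 0.095; range 0.0019 to 0.33). Among the other plastid-encoded genes they were lost for psbC (ArthCp018) without array 100 A (0.06; range 0.00053 to 0.06), petL (ArthCp040) without array 96 B or 100 A (0.077 and 0.15; range 0.0013 to 0.15) and atpH (ArthCp009) without array 96 A, 96 B or 100 A (0.058, 0.093 and 0.16; range 0.012 to 0.16). The same held for ndhA without array 100 A (0.093; range 0.0022 to 0.093) and ndhJ (ArthCp025) without array 96 B or 100 C (0.058 and 0.1; range 0.0099 to 0.1). Of 5 core histone genes 3 were lower (5 over the list alone, camera adjusted p = 0.0064; adjusted p = 0.19 with an estimated correlation), HTB11 (AT3G46030) by -0.54, HTB2 (AT5G22880) by -0.47 and HTB4 (AT5G59910) by -0.23. HTB4 lost its call without array 96 A, 96 C, 100 A, 100 B or 100 C (adjusted p = 0.082, 0.095, 0.12, 0.051 and 0.052; range over alternatives 0.011 to 0.12). Of the root marker list, examined here after values were seen, PYK10 stood at 1210 ± 79.5 in set 100 and 2280 ± 55.1 in set 96 (log2 difference -0.91, adjusted p = 0.016), and EXPA18 had a log2 difference of -0.7 (adjusted p = 0.025). PYK10 was not called without array 100 A (0.052) or with the pseudocount divided by 4 (0.051; range over the alternatives run 0.00016 to 0.052). Its arrays lay far apart, at 1147 to 1300 in set 100 and 2213 to 2317 in set 96. The adjusted p uses the spread pooled over all sets, including whole plants, where PYK10 ran from 6.82 to 49.5. With 4 times the pseudocount, which shrinks differences among low values, adjusted p was 0.00016. The lost calls therefore do not show that PYK10 varied within sets 96 and 100. EXPA18 was not called without array 96 A, 96 C, 100 A or 100 C (0.063, 0.083, 0.11 and 0.082; range over the alternatives run 0.0091 to 0.11). In all 4717 probe sets were called, 2746 higher and 1971 lower. With the arrays shifted to a common 75th percentile 47.9% of the calls were higher, and 48.8% after quantile normalization, against 58.2% as deposited.

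On sucrose, set ATGE_101 was compared with set 97. Across probe sets this difference and that of sets 100 and 96, which share no array, correlated at r = 0.674 (Spearman's rho 0.541). In all, 1462 probe sets were higher in both against 524 from independent lists, 1103 lower in both (349) and 160 opposite (862). THI2.1 stood at 213 ± 42.5 against 9.05 ± 1.54, a log2 difference of 3.78 (adjusted p = 2.6e-09). WSD1 (AT5G37300), a wax ester synthase, rose by 3.32, HIS1-3 by 3.27 and RXF26 (AT1G58430) by 3.0 (adjusted p = 4.7e-11, 3.7e-11 and 1.2e-09). CHX16 (AT1G64170), a cation/proton exchanger, changed by -2.31, NAI2 (AT3G15950), a protein of the ER body, by -2.2, ICL by -2.15 and SPCH (AT5G53210), which starts the stomatal lineage, by -2.11, from 33.6 ± 3.76 to 2.64 ± 1.01 (adjusted p = 7.8e-07, 1.7e-11, 1.5e-11 and 5.8e-07). AGL24 rose by 2.76 and AGL42 by 0.88, 2 of 3 floral promoters (3 over the list alone, camera adjusted p = 0.018; adjusted p = 0.075 with an estimated correlation). The cold list was higher in 3 of 3, COR15A by 2.29 (3 over the list alone, camera adjusted p = 0.00069; adjusted p = 0.075 with an estimated correlation). MCCA, IVD and MCCB were higher by 0.81, 1.14 and 0.46, 3 of 3 in their list (3 over the list alone, camera adjusted p = 0.011; adjusted p = 0.16 with an estimated correlation). Mitochondrion-encoded genes were higher in 8 of 12 (9 over the list alone and 1 lower, camera adjusted p = 0.0023; adjusted p = 0.075 with an estimated correlation). The jasmonate list was higher in 3 of 3 (3 over the list alone, camera adjusted p = 0.03; adjusted p = 0.43 with an estimated correlation). The PDF1.2 call (1.06, adjusted p = 0.036) was lost without array 97 A, 97 C, ATGE_101_A, ATGE_101_B or ATGE_101_C (adjusted p = 0.065, 0.12, 0.069, 0.098 and 0.059, range over alternatives 0.00063 to 0.12). Without arrays 24 A, 100 A and ATGE_101_A together, PDF1.2b and PDF1.2 were both not called (adjusted p = 0.06 and 0.083), which left THI2.1. Core histone genes were lower in 4 of 5 (5 over the list alone, camera adjusted p = 0.022; adjusted p = 0.39 with an estimated correlation), HTB11 by -0.66. A call was lost for HTB1 (AT1G07790) without array 97 B, 97 C, ATGE_101_A, ATGE_101_B or ATGE_101_C (0.17, 0.1, 0.1, 0.091 and 0.082; range 0.02 to 0.17), with adjusted p and the range over alternatives. PYK10 stood at 1000 ± 49.9 in set ATGE_101 and 2640 ± 142 in set 97 (log2 difference -1.4, adjusted p = 0.00045), while EXPA18 had a log2 difference of -0.54 (adjusted p = 0.068). EXPA18 was called without array ATGE_101_C (-0.85, adjusted p = 0.0046) and after quantile normalization (-0.64, adjusted p = 0.036). Without array ATGE_101_A its difference was -0.26 (adjusted p = 0.4). Other lists called between sets 100 and 96 were not called here. Those were the plastid-encoded lists of photosynthesis, NADH dehydrogenase-like complex and gene expression (camera adjusted p = 0.24, 0.42 and 0.24), the UGT family (0.45), serine carboxypeptidase-like genes (0.69), WRKY genes (0.42), genes numbered GH (0.39) and anthocyanin and flavonoid genes (0.35). Of these lists, the difference between the comparisons, which is that of the sucrose effects, was called for photosynthesis (camera adjusted p = 0.04; adjusted p = 0.84 with an estimated correlation). That call was also lost under the stricter filter, after quantile normalization and with a common 75th percentile (camera adjusted p = 0.051, 0.094 and 0.052). The actin 3' to 5' ratio was 8.62 ± 0.426 in set ATGE_101 and 3.8 ± 0.374 in set 97. That of GAPDH was 1.33 ± 0.194 and 1.35 ± 0.0878, and that of ubiquitin 2.31 ± 0.414 and 2.54 ± 0.0465. In all 5691 probe sets were called, 2952 higher and 2739 lower. The majority turned with the scaling: 51.9% were higher as deposited, 43.4% with a common 75th percentile (2538 higher and 3307 lower) and 45.5% after quantile normalization.

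Seedlings on medium at 20 °C were compared with those on soil at 23 °C, so substrate and temperature change together. The pigment pathway was lower in set 96 than in set 7. DFR (AT5G42800), dihydroflavonol reductase, stood at 23.4 ± 1.4 in set 96 and 651 ± 24.6 in set 7. The anthocyanin glycosyltransferases UGT75C1 (AT4G14090) and UF3GT (AT5G54060) and the acyltransferase AT5MAT (AT3G29590) changed by -4.62, -4.24 and -3.1 (adjusted p = 5.7e-12, 1.2e-11 and 6.8e-12), and UGT78D1 fell by 2.54 (adjusted p = 2.1e-13). All 7 measured members of the anthocyanin and flavonoid list were lower (7 over the list alone, camera adjusted p = 0.00024; adjusted p = 0.17 with an estimated correlation). The leucine breakdown genes were high on medium: MCCA rose by 3.13, IVD by 2.95 and MCCB by 1.54, 3 of 3 in the sugar starvation list (3 over the list alone, camera adjusted p = 0.005; adjusted p = 0.17 with an estimated correlation). All 8 autophagy genes were higher (8 over the list alone, camera adjusted p = 0.00024; adjusted p = 0.17 with an estimated correlation), with ATG8E (AT2G45170) at 483 ± 89.5 against 37.4 ± 2.75. Whole plants on soil differed from set 7 in the same direction in the pigment list (7 of 7 lower) and the autophagy list (8 of 8 higher). The same held there for plastid-encoded gene expression (13 of 19 lower, 1 higher) and ribosomal protein genes (3 of 3 lower), described below. These differences from set 7 are therefore not particular to medium. Both comparisons subtract the same arrays of set 7, so anything peculiar to set 7 would also give this agreement.

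The largest rise of a named gene on medium was in XTH18, from 2.2 ± 2.2, at the floor, to 871 ± 39.4 (log2 difference 6.64, adjusted p = 2e-12). GAT1_2.1 (AT1G15040), a glutamine amidotransferase, rose from 1.63 ± 0.128 to 249 ± 14.6, EXLA1 from 20.7 ± 3.03 to 784 ± 20.2. Further rises were in OSM34 (AT4G11650), an osmotin, from 2.14 ± 1.75 to 178 ± 10.8 and STZ (AT1G27730), a zinc finger protein of stress responses, from 18.1 ± 1.98 to 448 ± 17.2. WRKY6 rose by 4.64, WRKY53 (AT4G23810) by 2.79 and SAG101 (AT5G14930) by 2.05 while SAG29 fell by 1.26 (adjusted p = 2.2e-13, 7e-09, 5e-08 and 0.012). Thus 3 of 4 senescence genes were higher and 1 was lower (3 and 1 over the list alone, camera adjusted p = 0.12). SAG29 was not called with the pseudocount divided by 4 (adjusted p = 0.061, range over alternatives 4e-06 to 0.061). GH9C2 (AT1G64390) fell from 555 ± 34 to 51.3 ± 3.42, and rpoB (ArthCp014), a subunit of the plastid RNA polymerase, from 845 ± 112 to 101.1 ± 14.6. Plastid-encoded genes of gene expression were lower in 16 of 19 (16 over the list alone, camera adjusted p = 0.0023; adjusted p = 0.41 with an estimated correlation). Serine carboxypeptidase-like genes were lower in 11 of 15 and higher in 1 (11 and 1 over the list alone, camera adjusted p = 0.029; adjusted p = 0.35 with an estimated correlation). WRKY genes were higher in 4 of 5 and lower in 1 (4 and 1 over the list alone, camera adjusted p = 0.029; adjusted p = 0.35 with an estimated correlation).

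All 3 ribosomal protein genes were lower on medium, RPL4D by -1.18, RPL4A (AT3G09630) by -1.1 and RPL28A (AT2G19730) by -0.88 (3 over the list alone, camera adjusted p = 0.052). ICL stood at 131 ± 18 in set 96 against 0.78 ± 0.073 in set 7 (log2 difference 4.18, adjusted p = 2.4e-17). Of the root marker list, PYK10 (AT3G09260), a beta-glucosidase, was at 2280 ± 55.1 in set 96 and 747 ± 38.4 in set 7 (adjusted p = 2.6e-05), and EXPA18 (AT1G62980) at 16.3 ± 2.45 and 12.1 ± 5.15 (adjusted p = 0.21). The GAPDH 3' to 5' ratio was 0.933 ± 0.0452 in set 7 and 1.41 ± 0.131 in set 96, and set 7 lay below all other arrays, at 0.897 to 0.984. The other control ratios went the opposite way. Actin was at 5.96 ± 0.613 in set 7 and 4.12 ± 1.92 in set 96, and ubiquitin at 3.93 ± 0.369 and 2.46 ± 0.224. In all 10948 probe sets were called, 4696 higher and 6252 lower on medium, of which 2082 and 1810 changed at least 2-fold. Set 7 correlated with set 96 at a mean r of 0.779 and with set 97, on sucrose, at 0.837. With set 100 it was 0.757 and with set ATGE_101, on sucrose, 0.769.

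Whole plants of sets 22, 23 and 24 were compared with the soil seedlings of set 7 under the same regime; their means are over 9 arrays (n = 9). The chitinase CHI rose by 4.39 (adjusted p = 2.1e-10). RING1 (AT5G10380), a ubiquitin ligase, stood at 1019 ± 210 against 54.3 ± 7.59, and CYP71B23 (AT3G26210), a cytochrome P450, at 116 ± 36.7 against 10.9 ± 1.39. PDF1.2, PDF1.2b and THI2.1 rose by 2.69, 2.72 and 2.34 (adjusted p = 2e-07, 3.4e-06 and 2.2e-08), 3 of 3 in the jasmonate list (3 over the list alone, camera adjusted p = 0.087), and SAL2 by 2.66 (adjusted p = 2.7e-09). The cold list was higher in 3 of 3, COR47 by 2.13, COR15A by 2.25 and COR15B by 1.8 (3 over the list alone, camera adjusted p = 0.011; adjusted p = 0.3 with an estimated correlation). Anthocyanin genes were low here too: DFR stood at 44.1 ± 16.5, UF3GT at 25.3 ± 7.54, UGT75C1 at 26.8 ± 10.4, AT5MAT at 12.4 ± 3.19 and UGT78D1 at 143 ± 39.7. In their list 7 of 7 members were lower (7 over the list alone, camera adjusted p = 4.1e-06; adjusted p = 0.1 with an estimated correlation). All 8 autophagy genes were higher (8 over the list alone, camera adjusted p = 0.00013; adjusted p = 0.12 with an estimated correlation), ATG8F (AT4G16520) by 1.54 and ATG8C (AT1G62040) by 1.15.

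The largest fall of a named gene was in PYK10, from 747 ± 38.4 in seedlings to 25.2 ± 15.7 in plants (log2 difference -4.71, adjusted p = 3.9e-13), while the other measured root marker, EXPA18, had a log2 difference of 0.42 (adjusted p = 0.055). JAL22 (AT2G39310), a jacalin lectin, fell from 128 ± 12.8 to 9.82 ± 3.91. Ribosomal protein genes were lower in 3 of 3 (3 over the list alone, camera adjusted p = 0.087), RPL4D by -0.77, RPL4A by -0.67 and RPL28A by -0.27. The RPL28A call was lost without array 7 C (adjusted p = 0.065) and after quantile normalization (0.084; range over alternatives 0.0014 to 0.084). Plastid-encoded genes of gene expression were lower in 13 of 19 and higher in 1 (14 and 1 over the list alone, camera adjusted p = 0.00026; adjusted p = 0.4 with an estimated correlation), rpoB by -2.66. The GAPDH 3' to 5' ratio was 1.53 ± 0.232, 1.16 ± 0.0566 and 1.83 ± 0.856 in sets 22, 23 and 24, all above set 7. The actin ratio was 9.51 ± 2.0, 10.1 ± 1.66 and 9.01 ± 1.14 against 5.96 ± 0.613. The ubiquitin ratio went the other way, with means of 3.455, 3.058 and 3.795 against 3.926 in set 7. In all 10082 probe sets were called, 5147 higher and 4935 lower in plants. The majority turned with the scaling, from 51.1% higher as deposited to 46.2% with a common 75th percentile and 47.4% after quantile normalization.

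**Figure D2:**
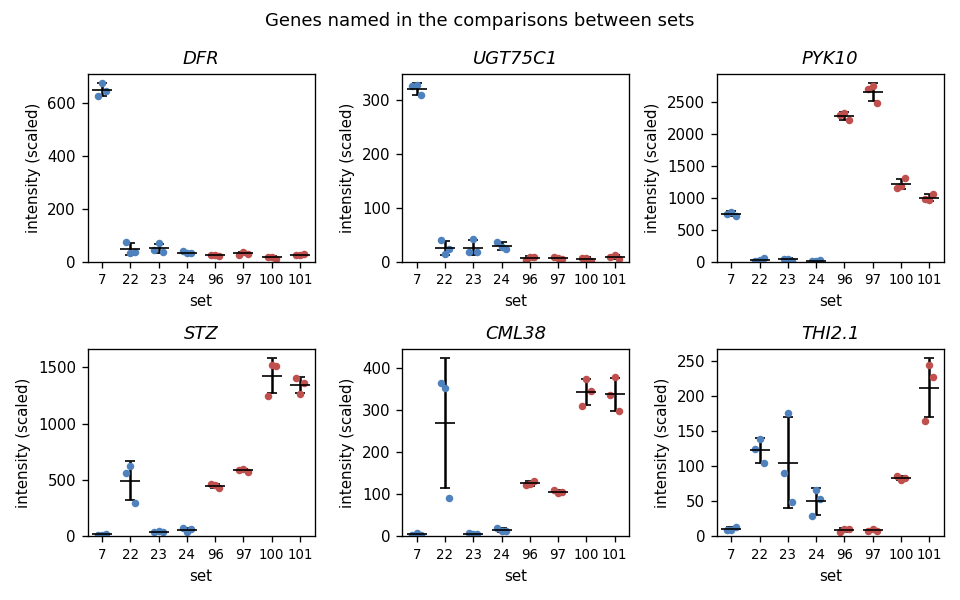
Intensity (scaled, linear axis) of 6 genes named in the comparisons between sets; blue points are arrays of plants on soil, red points arrays of seedlings on medium, and the horizontal line and bars are mean ± SD of 3 arrays. DFR and UGT75C1 were highest in set 7 (DFR 651 ± 24.6), PYK10 was lowest in sets 22 to 24, and STZ and CML38 were higher in set 22 than in sets 23 and 24.

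The sets of whole plants share their label, and the question is whether they differ. CML38 (AT1G76650), a calmodulin-like protein, was at 269 ± 155 in set 22, 6.43 ± 1.24 in set 23 and 15.6 ± 4.31 in set 24. STZ was at 493 ± 173, 42.7 ± 3.19 and 61.1 ± 15.8, EXLA1 at 628 ± 74.4, 75.6 ± 21.9 and 65.4 ± 28.3, and EXO (AT4G08950), which promotes growth, at 1150 ± 423, 176 ± 28.9 and 175 ± 12.2. Between sets 24 and 22 the log2 differences were -3.41, -2.84, -3.21 and -2.62 (adjusted p = 9.7e-08, 8.4e-10, 7.1e-10 and 6e-10). Within set 22, array 22 C stood apart, with the lowest mean r with its replicates of all arrays, 0.9695. CML38 was at 90.6 in it against 364 and 353 in 22 A and 22 B, and STZ at 297 against 558 and 624.5. EXLA1 was not lower there (713 against 596.5 and 575). PUB23 (AT2G35930), a ubiquitin ligase, and XTH18 changed by -2.37 and -2.3 (adjusted p = 2.5e-05 and 2e-04). The genes that rose did so by less: IAGLU (AT4G15550), an indole-3-acetate glucosyltransferase, by 1.26, WSD1 by 1.19 and AFR (AT2G24540), an F-box protein of far-red light signalling, by 1.16. HIS1-3 rose by 1.04, EXPA8 by 1.01 and GAMMA-VPE (AT4G32940), a vacuolar processing enzyme, by 0.92 (adjusted p = 9.1e-06, 0.00015, 5.3e-05, 0.00044, 0.00077 and 1.2e-05).

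Of 4 senescence genes WRKY53 was lower in set 24, by -1.83 (adjusted p = 5.2e-05), and the list was called (1 lower over all genes, 2 over the list alone, camera adjusted p = 0.023; adjusted p = 0.23 with an estimated correlation). Of 7 calmodulin-like genes 4 were lower (4 over the list alone, camera adjusted p = 0.0051; adjusted p = 0.097 with an estimated correlation), CML38, CML37 (AT5G42380), CML23 (AT1G66400) and CML42. Without array 22 B or 24 A the calls of CML23 (adjusted p = 0.093 and 0.095) and CML42 (0.11 and 0.091) were lost, and that of CML42 also without 24 B (0.065). Of 5 xyloglucan endotransglucosylases 3 were lower (3 over the list alone, camera adjusted p = 0.0051; adjusted p = 0.083 with an estimated correlation), XTH18, XTH19 (AT4G30290) and XTH33 (AT1G10550). Of 13 expansins 3 were higher and 2 lower (3 and 3 over the list alone, camera adjusted p = 0.69). The lower members among 5 WRKY genes were WRKY53 and WRKY22 (AT4G01250) (2 over the list alone, camera adjusted p = 0.0051; adjusted p = 0.21 with an estimated correlation). Of 15 cytochrome P450 genes 4 were higher (4 over the list alone, camera adjusted p = 0.03; adjusted p = 0.31 with an estimated correlation), CYP71B26 (AT3G26290) by 0.8. Calls were lost for CYP71B28 (AT1G13090) without array 24 A (0.053; range 0.0036 to 0.093) and CYP71B34 (AT3G26300) without array 24 A (0.074; range 0.0099 to 0.15), with adjusted p and the range over alternatives. Among 19 plastid-encoded genes of gene expression none was called (0 over the list alone, camera adjusted p = 0.0082; adjusted p = 0.54 with an estimated correlation). THI2.1 changed by -1.24 and COR47 by -0.66 (adjusted p = 0.0045 and 0.00019), each 1 of 3 in its list (1 over the list alone, camera adjusted p = 0.063 and 0.14). UGT78D1 rose by 0.56 (adjusted p = 0.004), 1 of 7 (1 over the list alone, camera adjusted p = 0.49). With only the 6 arrays of sets 22 and 24 in the fit, 595 probe sets were called in place of 2493, 212 higher and 383 lower. There EXPA8, XTH18, WRKY53 and UGT78D1 lay just past the threshold (adjusted p = 0.053, 0.052, 0.052 and 0.052), and XTH19, XTH33, CML37, CML23 and CML42 at 0.073, 0.14, 0.17, 0.075 and 0.13. Over all alternatives adjusted p ran from 0.0019 to 0.11 for CML23 and from 0.018 to 0.13 for CML42, and for the others the highest was the value given here. Array 24 A had a GAPDH 3' to 5' ratio of 2.81, the highest of all arrays. Of the 2493 calls 1425 were higher and 1068 lower in set 24, 57.2% higher as deposited and 44.9% with a common 75th percentile, while 55 rose and 367 fell at least 2-fold.

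Between sets 23 and 22, CML38 changed by -4.16, STZ by -3.27, EXLA1 by -2.98 and EXO by -2.61 (adjusted p = 4.7e-09, 1e-10, 2e-09 and 5.5e-10), and AFR, GH9C2, HIS1-3 and EXPA8 rose by 1.29, 0.97, 0.96 and 0.95 (adjusted p = 1.4e-05, 3.2e-06, 0.00093 and 0.0013). Of 4 senescence genes 3 were lower (3 over the list alone, camera adjusted p = 0.0019; adjusted p = 0.11 with an estimated correlation), WRKY53, SAG101 and WRKY6. SAG101 lost its call without array 22 A or 22 B (adjusted p = 0.052 and 0.061) and WRKY6 without 22 A or 23 C (0.079 and 0.053; range over alternatives 0.0015 to 0.061 and, for WRKY6, range over alternatives 0.0061 to 0.079). Of 5 WRKY genes 3 were lower (3 over the list alone, camera adjusted p = 0.00024; adjusted p = 0.11 with an estimated correlation), WRKY22, WRKY53 and WRKY6. Of 7 calmodulin-like genes 3 were lower (4 over the list alone, camera adjusted p = 0.00076; adjusted p = 0.066 with an estimated correlation), CML38, CML37 and CML42. The xyloglucan endotransglucosylases, 1 higher and 1 lower of 5 (1 and 1 over the list alone), and the expansins, 4 higher and 3 lower of 13 (5 and 3 over the list alone), were not called as lists (camera adjusted p = 0.44 and 0.8). In all 2080 probe sets were called, 969 higher and 1111 lower in set 23. With only these 6 arrays in the fit 746 were called, 224 higher and 522 lower. EXPA8, SAG101, CML37 and CML42 were then not called (adjusted p = 0.092, 0.055, 0.14 and 0.1).

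Sets 24 and 23 differed little. IAGLU and GAMMA-VPE were higher in set 24, by 0.87 and 0.81 (adjusted p = 0.011 and 0.0038), as were SUFE2 (AT1G67810) and RR16 (AT2G40670), a response regulator, by 0.68 and 0.64 (adjusted p = 0.036 and 0.043). GSTU20 (AT1G78370) changed by -0.67, XTH32 (AT2G36870) by -0.5, and NDC1 (AT5G08740) and CLPP4 (AT5G45390), of the chloroplast, by -0.37 and -0.37 (adjusted p = 0.0088, 0.021, 0.023 and 0.035). The xyloglucan endotransglucosylase list was lower, with XTH32 the called member of 5 (3 over the list alone, camera adjusted p = 0.0031). It kept its call with an estimated correlation (adjusted p = 0.034) but not without the filter on low values (camera adjusted p = 0.066). The calls here were fragile: 132 probe sets were called, 65 higher and 67 lower, 44 without array 24 C, 76 without array 23 B and 370 without array 24 B. With only these 6 arrays in the limma fit 0 were called and 1273 had an unadjusted p under 0.05, and all 8 genes named here had adjusted p between 0.44 and 0.52. SUFE2 lost its call without array 23 A, 23 C or 24 C (0.12, 0.096 and 0.17), XTH32 without 23 A, 23 C, 24 A or 24 C (0.063, 0.051, 0.064 and 0.074). The same held for NDC1 without the same arrays (0.053, 0.086, 0.061 and 0.076), for RR16 without 23 A, 23 B, 24 A, 24 B or 24 C (0.091, 0.17, 0.085, 0.064 and 0.077) and for CLPP4 without any single array (0.056 to 0.092). Over all alternatives adjusted p ran from 0.018 to 0.52 for SUFE2, 0.0041 to 0.51 for XTH32, 0.013 to 0.52 for NDC1, 0.0096 to 0.51 for RR16 and 0.015 to 0.52 for CLPP4. The share of higher calls was 49.2% as deposited, 34% with a common 75th percentile and 39.1% after quantile normalization. Any difference among sets 22, 23 and 24 was called for 2686 probe sets.

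**Figure D3:**
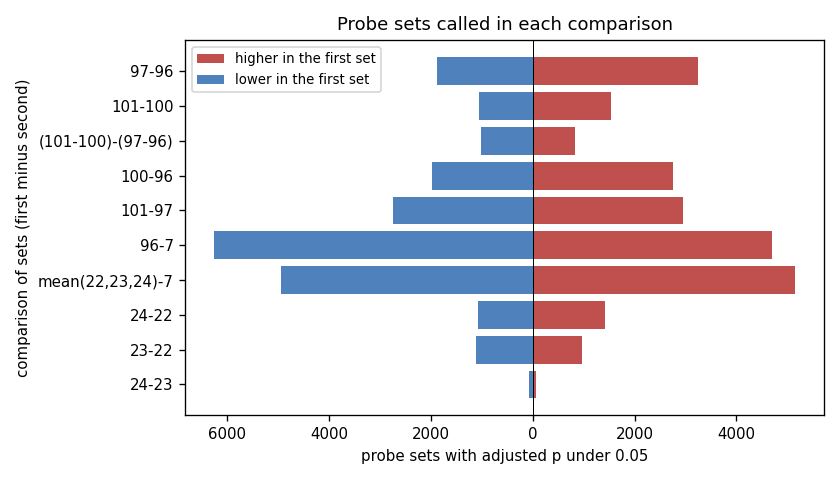
Number of probe sets with adjusted p under 0.05 in each comparison (horizontal axis, counts, with lower calls drawn to the left of 0 and higher calls to the right); each row is named as first set minus second set. The bars run from 132 calls between sets 24 and 23 to 10948 between sets 96 and 7.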

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

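The comparison of the sucrose effects between the pairs of sets and the count of other splits were planned, while the list of plastid-encoded genes was drawn up after the annotation was read and before any list test. The effect of sucrose differed between the pairs (sets ATGE_101 and 100 against 97 and 96) by the test of the difference itself for 1855 probe sets. Of 100 splits of the 12 arrays, the real one included, 4 gave as many calls, and the highest other split gave 2347. That share is under 0.05, but its 95% interval from the 99 other splits, 0.0063 to 0.086, is not. These splits also mix arrays of all 4 sets, and so carry differences between sets, such as the 4717 calls between sets 100 and 96. The share therefore cannot decide whether the difference of the sucrose effects arose by chance, and chance is not excluded. RNA quality stays open as well: set ATGE_101 had an actin 3' to 5' ratio of 8.62 against 4.12, 3.8 and 3.6 in sets 96, 97 and 100. Its GAPDH ratio was 1.33 against 1.41, 1.35 and 1.39 and its ubiquitin ratio 2.31 against 2.46, 2.54 and 2.32, neither of them raised. No test separates the actin difference from the effect of sucrose in that set. The log2 difference of the effects was 2.37 for OCT1, 1.96 for UGT73B4, 1.87 for ICL, 1.86 for GILT, -1.62 for NRT2.5, -1.35 for SAL2, -1.29 for EXPA8 and -1.25 for CSLA03. The call of SAL2 was lost without array 96 A, 96 C, 97 A, 97 B, 97 C, 100 A, 100 C or ATGE_101_C (adjusted p = 0.076, 0.056, 0.055, 0.069, 0.05, 0.067, 0.073 and 0.083; range over alternatives 0.001 to 0.083). The mean difference was 0.82 for the sugar starvation list and 0.17 for the plastid-encoded photosynthesis genes; neither list kept its call with an estimated correlation (adjusted p = 0.14 and 0.84).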

How the results depend on the processing

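The alternative without arrays 24 A, 100 A and ATGE_101_A was chosen after seeing the data; the others were planned. No named gene and no called list reversed its direction under any alternative run. Of 279 named results, calls were lost for 11 with the pseudocount divided by 4, 3 with 4 times it, and 23 without the filter. They were lost for 0 of 254 under the stricter filter, 17 after quantile normalization, 7 with a common 75th percentile, 32 with only the groups compared and 1 with a trend and robust fitting. With the replicate letter as a block 8 were lost and 107 probe sets were called between sets 24 and 23; no count moved beyond 1.5 times, and arrays of different sets that share a letter showed no common pattern (84 pairs of arrays, r from -0.18 to 0.16). With only the groups compared, which leaves fewer arrays to estimate the spread, 3076 were called for the difference of the sucrose effects. The counts were 595 for set 24 against 22, 746 for 23 against 22 and 841 for any difference among sets 22, 23 and 24. For 24 against 23 the count was 0 (1273 at an unadjusted p under 0.05, limma). For 97 against 96 the count rose from 5118 to 6028. The spread changes in these fits along with the number of arrays. That rise therefore cannot show how much of the lower counts among whole plants comes from fewer arrays. Arrays of the same set correlated at a mean r of 0.975, 0.983 and 0.978 in sets 22, 23 and 24, against 0.987 to 0.99 in the medium sets. The spread pooled over all sets may thus be too small for sets 22, 23 and 24, and their main counts too high. For single genes it may instead be too large for the medium sets. PYK10 and XTH18 are examples, with low and variable values in whole plants. Without the filter 76 were called for 24 against 23; the cause was not tested.

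Leaving out 1 array gave 4056 to 4352 calls for 97 against 96, 1764 to 2063 for ATGE_101 against 100, 1297 to 1562 for the difference of these effects, and 3737 to 4060 for 100 against 96. It gave 4690 to 4974 for ATGE_101 against 97, 10400 to 10489 for 96 against 7, 9137 to 10218 for whole plants against 7, 1811 to 2859 for 24 against 22, 1551 to 2394 for 23 against 22 and 1997 to 2985 for any difference. For 24 against 23 it gave 44 (without 24 C) to 370 (without 24 B), and 76 without 23 B. In 182 of 1938 cases a named result lost its call when 1 array was left out. Without arrays 24 A, 100 A and ATGE_101_A 32 did, and no count moved beyond 1.5 times. Of 53 called lists 50 lost the call with an estimated correlation, 18 of 51 under the stricter filter, 6 without the filter, 6 after quantile normalization, and 1 each with 4 times the pseudocount and a common 75th percentile. Signal near the floor limits the differences of low genes, which shrink as the pseudocount grows.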

Other observations

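The tests of plastid-encoded transcripts and of sets ATGE_101 and 97 for the mitochondrial pattern were chosen after the result was seen, as were that of its members well above the floor and those of the calmodulin-like and WRKY genes without array 24 A and after rescaling. So was the use of a 95% bootstrap interval over transcripts, which are not independent, for the tests of these patterns. An explanation is argued against where the interval lies wholly outside the values it needs. This rule replaced a stricter one, under which some of the mitochondrial tests stayed open. The other tests were set down first. Tetraspanins, membrane proteins with several spans, were higher in set 96 than in set 7 for 6 of 8 genes and lower for 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.12). TET8, chosen after its values were seen, had log2 differences of 3.16 there, 1.93 in whole plants against set 7, and -1.55 and -1.77 in sets 24 and 23 against set 22 (adjusted p = 4.2e-14, 1e-11, 1.1e-07 and 1.3e-08). All 5 RALF-like peptide genes were higher in whole plants than in set 7 (5 over the list alone, camera adjusted p = 0.1). HTB1, a histone H2B gene also chosen after its values were seen, was lower in sets 96 and whole plants than in set 7, by -1.37 and -0.78 (adjusted p = 5.6e-09 and 1.5e-06).

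Across 15471 probe sets, 7 relations between comparisons were computed; probe sets are not independent replicates, and those that share an array are not given. The difference of set 96 from set 7 correlated with that of set 22 from set 24 at r = 0.436 (Spearman's rho 0.248) and with that of set 22 from set 23 at 0.526 (0.363). The sucrose effects correlated with set 24 minus set 22 at 0.324 (0.272) for the first pair and 0.243 (0.265) for the other.

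The lists of calmodulin-like and WRKY genes were called lower in sets 24 and 23 than in set 22 at the preset correlation. With an estimated correlation neither was called (adjusted p = 0.097 and 0.066 for calmodulin-like genes, 0.21 and 0.11 for WRKY genes), so the pattern is a tentative one. The first was also not called in set 24 under the stricter filter (0.076). As its cause, the RNA quality of array 24 A is argued against: the median log2 difference of the 12 genes without that array was 1.19 times that with it in set 24 against 22 (95% interval 0.773 to 2.57), where this cause needed under 0.25. Without 24 A the calls of CML23 and CML42 were lost (adjusted p = 0.095 and 0.091, ranges over alternatives 0.0019 to 0.11 and 0.018 to 0.13). Their log2 differences were then -0.63 and -0.33, against -0.81 and -0.36 with that array. Scaling is argued against by the median after quantile normalization and with a common 75th percentile, at lowest 0.961 times that as deposited (0.916 to 1.02, set 23 against 22), where it needed under 0.5. The tests set down first ran over all called probe sets and do not measure these genes: the median ratio without and with array 24 A was 0.98, and 2324 were called after quantile normalization against 2493. A response to touch, wounding or calcium at or before harvest may contribute, but only PUB22 and PUB24 of the touch list lay outside the lists and named genes, with a median log2 difference of -0.825 over these 2, too few to decide. The list was drafted after the named genes were seen. Developmental stage, which the label's word drift leaves unspecified, stays open and was not tested.

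Mitochondrion-encoded transcripts were higher in set 100 than in set 96, with a median log2 difference of 0.834. Carry-over of organelle nucleic acid in general is argued against by the plastid-encoded photosynthesis transcripts, with a median of -0.321 (95% interval -0.363 to -0.28). Values near the floor as the whole cause are argued against: with 4 times the pseudocount the median was 0.589, a ratio of 0.706 with an interval of 0.601 to 0.89, where this cause needed a ratio under 0.5. The 10 members with a mean above 27 in both sets had a median of 0.765 (0.39 to 1.04). A part played by the floor stays open, since the ratio set down first against it, 2 divided by 3, lies inside the interval. An error of these 6 arrays alone is argued against by other arrays, those of set ATGE_101 against 97, with a median of 0.596 (0.161 to 0.794 over transcripts, 0.432 to 0.719 over 9 pairs of arrays). The stricter bound first set against this cause lies inside the interval over transcripts, but below all 9 pairs. There the list was not called with an estimated correlation (adjusted p = 0.075). What sets 96 and 97 share against sets 100 and ATGE_101 stays open. No biological explanation was tested, as the labels give both sets the same conditions.

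Set 7 stood apart from the other sets in many probe sets. Scaling is argued against by 10869 calls between sets 96 and 7 after quantile normalization, against 10948. A bias towards the 3' end stays open, as a single array carries the test: the difference of array 24 A from 24 B and 24 C correlated with set 96 minus set 7 at r = 0.149 across probe sets. The control ratios disagreed as well: that of GAPDH was lower in set 7 than in set 96, while those of actin and ubiquitin were higher. A candidate explanation for part of the difference is sugar supply. The sucrose effect in sets ATGE_101 and 100 correlated with set 7 minus set 96 at r = 0.335 (Spearman's rho 0.294). Such a correlation is not specific to sugar. Set 96 minus set 7 also correlated with set 22 minus set 23 (r = 0.526, rho 0.363) and set 22 minus set 24 (0.436, 0.248), all plants on soil. Set ATGE_101 also stood out by its actin 3' to 5' ratio, 8.62 against 3.6 in set 100, though not by its GAPDH or ubiquitin ratio. Substrate and temperature change together between these sets and stay open.

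Other splits of the same arrays were counted for each comparison. For 3 against 3 arrays the 10 splits are too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many calls. The real count and the highest other were 5118 and 1 for 97 against 96, 2578 and 0 for ATGE_101 against 100, 4717 and 0 for 100 against 96, 5691 and 0 for ATGE_101 against 97, and 10948 and 0 for 96 against 7. They were 2493 and 346 for 24 against 22, 2080 and 179 for 23 against 22, and 132 and 87 for 24 against 23. Of 100 splits, 1 gave as many calls as the 10082 between whole plants and set 7, where the highest other was 3469. Again 1 gave as many as the 2686 for any difference among sets 22, 23 and 24, where it was 1052. A random grouping of these arrays can be excluded for both. Chance differences between the cultures or harvests of the sets cannot, since the labels do not say whether arrays of a set come from separate cultures.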
